A study of Mus musculus with 16 samples.

How the data were processed

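Chromatin immunoprecipitation and sequencing (ChIP-seq) was done on neural stem cells cultured as neurospheres from the telencephalic cortex of E14.5 mouse embryos. Per the labels, cells were plated on Matrigel and fixed with 1% formaldehyde, and libraries were made with 14 PCR cycles and read as single reads of 50 bp. The series holds 16 samples. Island lists of 13 libraries were used: H3K4me1, H3K4me3, H3K27ac, H3K27me3, H3K36me2 and H3K36me3 in wild-type and in Setd5+/- cells, and SETD5-V5 in wild-type cells. The 3 input samples are not analysed here.

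Per the submitters' processing notes, reads were checked with FastQC, aligned with Bowtie2 2.2.3 to GRCm38 (mm10), and enriched islands were called with SICER 1.1. Per the file headers, the H3K36me2, H3K36me3 and SETD5-V5 lists used a window of 800 bp, a gap of 2400 bp and a false discovery rate of 0.01. The other 8 lists have no settings in their headers, and their island widths are multiples of 200 bp. The deposited whole number beside each island was read as the authors' counts of reads per island, a reading taken from the values since no header names the column. No normalisation of these counts is recorded, and whether the inputs served as controls, and the total reads of each library, are not given in the sources used here. Depth outside the islands is therefore unknown. Reads inside islands ranged from 1019278 to 5093126 per library. Shares of island reads carry 95% Wilson intervals from scipy, which cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

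All computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. Genotypes were compared within each mark, with 1 library per group. The comparisons, gene lists, rule for named genes and 26 alternatives were fixed before the data were examined. No list had overlapping or touching islands. A wild-type island counted as lost when no Setd5+/- island of the same mark overlapped it by 1 bp or more, and as gained in the reverse case. Covered length and mean width are given because islands were called separately in each library.

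Genes were 21887 protein-coding genes of the RefSeq annotation of GRCm38. The annotation used has no strand, so promoters were replaced by gene ends, a change from the planned transcription start sites. A gene counted as marked at an end with an island within 1 kb of either annotated end, and as marked over the body with islands over at least 25% of its span, for the 16853 genes of at least 5 kb. SETD5-V5 islands were compared with 1000 circular shifts along each chromosome. Genes of at least 5 kb with SETD5-V5 at an end were compared with 10000 random lists of equal size matched on 10 classes of gene length and 5 classes of wild-type coverage, and gene lists with 10000 random lists matched on gene length. Random lists were drawn from all genes of a class, without leaving out the genes they were compared with. Results outside the central 95% were taken as set apart. Random lists of promoter marks were not matched on the wild-type mark, so the share of marked genes in 1 genotype only, a comparison chosen after the values were seen, stands beside them. These percentiles describe the libraries at hand and are no test between genotypes. The density of shared islands is the log2 ratio of reads per kb, relative to the median over autosomes other than 1, 4 and 15, a comparison chosen after the chromosome values were seen.

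The 15 gene lists were neural stem cell and radial glia, neuronal differentiation, synapse, axon guidance and adhesion, H3K36 methylation enzymes and readers, HDAC3-NCoR and PAF1 complexes, Polycomb and Trithorax, Hox clusters, astrocyte and oligodendrocyte, microglia and blood, endothelium and mesenchyme, non-neural lineage regulators, ribosomal proteins, RNA polymerase II and splicing, and cell cycle. All 391 entries were found in the annotation. Named genes were the 10 with the largest fall and the 10 with the largest rise in H3K36me3 and in H3K36me2 body coverage. For H3K4me3, H3K27ac and H3K27me3 they were the 5 genes marked in 1 genotype only with the longest coverage within 5 kb of an end, in each genotype. Ties were broken by the change in covered length and then by symbol. Setd5, the 10 SETD5-V5 islands with most reads, and list members with the largest change complete the rule, and predicted genes were skipped. Not every gene that the rule gives is printed.

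The steps were tested on simulated changes of the real lists. When 200 islands were removed from and added to each wild-type list, 100% were recovered. Added islands were placed clear of all others, so this checks the code and not how well real changes are found. Of 200 random gene lists, 5.0% lay outside the central 95% for H3K36me3, and 100% of lists given a fall of 20 percentage points were found. That fall exceeds the largest H3K36me3 change of a list in the main setting, −12.9 for ribosomal protein genes. How often changes of the sizes seen would be found was not tested. Alternatives were a stricter island threshold without the lowest 25% of each list by reads, 50% reciprocal overlap, autosomes only, equal covered length of both genotypes, islands within 3 kb merged, gene end windows of 2.5 kb or the end base itself, body shares of 10% and 50%, genes that overlap no other gene, SETD5-V5 anywhere in the gene, matching on length alone and no matching. Leaving out chromosomes 1, 4, 15, X and Y was chosen after seeing the data.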

Results

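The study asks whether SETD5, a chromatin protein described in the series title as a methyltransferase of histone H3 lysine 36, shapes histone marks in neural stem cells. Lists of enriched regions, called islands, were compared for 6 histone marks in wild-type and Setd5+/- neural stem cells from the cortex of E14.5 mouse embryos. A further list holds the islands of V5-tagged SETD5 in wild-type cells. Each group has 1 library and no replicates, so differences between genotypes are given as values without a p-value, and counts marked in 1 genotype only describe these libraries.

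H3K36me3, the mark of transcribed gene bodies, covered 190 Mb in wild type and 202 Mb in Setd5+/- cells, in 8389 islands of mean width 22672 bp and 9452 islands of mean width 21352 bp. H3K36me2 covered 69.1 Mb in 4566 wild-type islands of mean width 15131 bp and 121 Mb in 4167 Setd5+/- islands of mean width 29093 bp. The repressive mark H3K27me3 covered 64.4 Mb in wild type and 47.1 Mb in Setd5+/- cells, with mean widths of 3256 and 2509 bp. The enhancer mark H3K4me1 covered 67.1 and 48.5 Mb, with mean widths of 1891 and 2002 bp. The promoter mark H3K4me3 covered 43.5 and 46.6 Mb, with mean widths of 1909 and 2001 bp, and H3K27ac, found at active promoters and enhancers, covered 36.3 and 39.8 Mb, with mean widths of 1948 and 2283 bp. SETD5-V5 covered 121 Mb in 6143 islands of mean width 19719 bp. Reads inside islands ran from 1019278 for Setd5+/- H3K27ac to 5093126 for Setd5+/- H3K4me3.

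Setd5 itself lies on chromosome 6 (113077262 to 113153432) and was covered by H3K36me3 over 98.5% of its span in wild type and 73.3% in Setd5+/- cells. H3K36me2 covered 24.2% of the gene in wild type and none of it in Setd5+/- cells. H3K4me3 covered 8.85% and 11.7% of the span and H3K27ac 11.8% and 12.6%, and no H3K27me3 island touched the gene in either genotype. A single SETD5-V5 island of 56.0 kb covered 69.1% of the gene. Islands do not measure the transcript or the allele, so these values are no check of the genotype.

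The difference between the genotypes varied by chromosome. Chromosome 1 had 6.96 Mb of H3K36me2 in wild type and 63.1 Mb in Setd5+/- cells, and its share of the reads inside H3K36me2 islands was 10.0% (95% Wilson interval 9.99 to 10.1) and 54.6%. The other marks on chromosome 1 also covered more in Setd5+/- cells, 14.9 against 26.1 Mb for H3K36me3, 2.58 against 6.25 Mb for H3K27ac, 3.10 against 7.39 Mb for H3K27me3 and 2.72 against 3.92 Mb for H3K4me3. H3K4me1 on this chromosome was 1.67 times as long. Chromosome 15 had more coverage of every mark too, from 1.12 times for H3K4me1 to 3.92 times for H3K36me2, and chromosome 4 had 3.10 times as much H3K36me2. Across the 16 other autosomes H3K36me2 covered 55.0 Mb in wild type and 33.6 Mb in Setd5+/- cells, a ratio of 0.611, while H3K36me3 covered 151.9 and 148.2 Mb, a ratio of 0.976. The ratio on those autosomes was 1.04 for H3K4me3, 0.948 for H3K27ac, 0.792 for H3K27me3 and 0.606 for H3K4me1. Of those autosomes, only chromosome 13 had more H3K36me2 in Setd5+/- cells, 5.99 against 5.63 Mb. On chromosome X, H3K27me3 covered 22.2 Mb in wild type and 6.71 Mb in Setd5+/- cells.

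**Figure D1:**
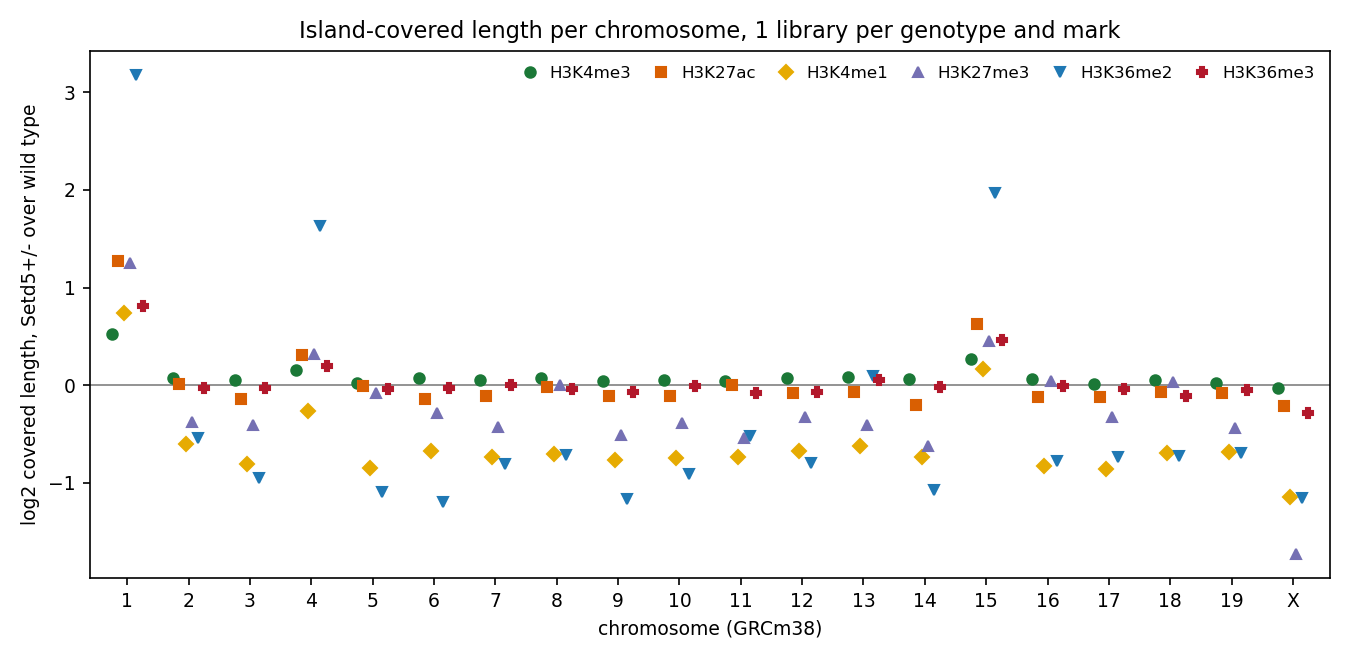
Log2 ratio of covered length, Setd5+/- over wild type, for each chromosome (x axis) and mark (points), 1 library per group. Chromosome 1 lies above the 16 other autosomes in all 6 marks, with H3K36me2 highest at 3.18.

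The reads per kb of islands present in both genotypes were also higher on these chromosomes in Setd5+/- cells. Relative to the 16 other autosomes, the median log2 ratio over islands of chromosome 1 was 0.30 for H3K4me3, 0.25 for H3K27ac, 0.21 for H3K4me1, 0.23 for H3K27me3, 0.31 for H3K36me2 and 0.34 for H3K36me3. On chromosome 15 it lay between 0.09 and 0.18. On chromosome 4 it was 0.33 for H3K4me3 between 30 and 80 Mb and 0.00 on the rest of the chromosome, a split chosen after the values were seen.

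**Figure D2:**
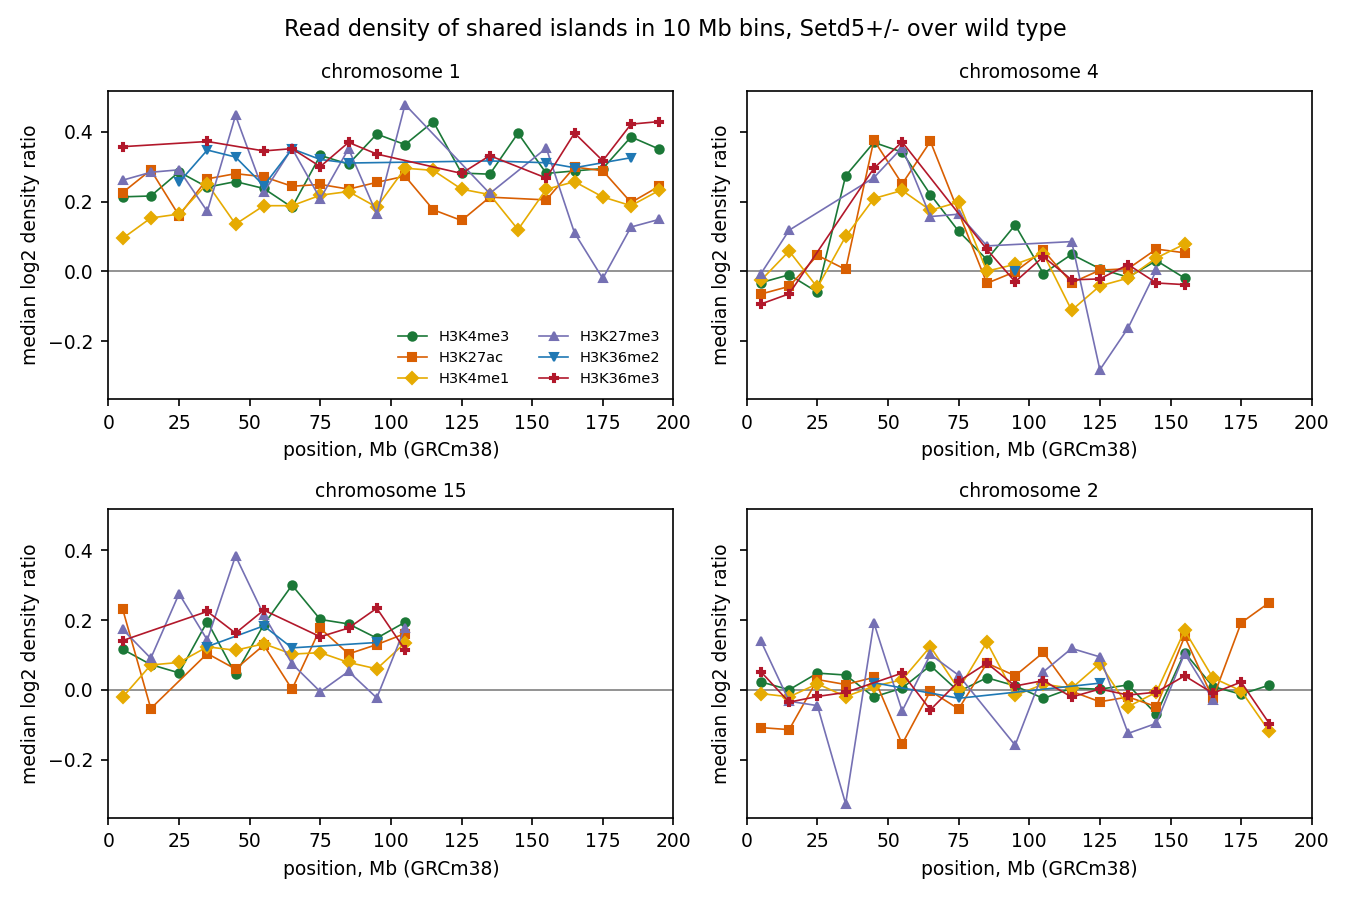
Median log2 ratio of reads per kb of shared islands, Setd5+/- over wild type, in windows of 10 Mb along the chromosomes, relative to the autosomes other than 1, 4 and 15. Values are mostly raised along chromosomes 1 and 15 and between 30 and 80 Mb of chromosome 4. On chromosome 1, 16 of the 17 windows drawn were above 0 for H3K27me3, and all were for each other mark. On chromosome 15 the lowest share was 9 of 11, also for H3K27me3. H3K27ac was 0.006 between 30 and 40 Mb of chromosome 4.

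By an overlap of 1 bp, most H3K36me3 islands were shared, with 908 of the wild-type islands (10.8%) lacking a Setd5+/- island and 1853 Setd5+/- islands (19.6%) lacking a wild-type one. Wild-type islands without a partner had a median of 115 reads, against 215 for those with one. With 50% reciprocal overlap the islands without a partner numbered 2930 and 3993. For H3K36me2, 2827 wild-type islands (61.9%) and 2688 Setd5+/- islands (64.5%) had no partner. On chromosome 1 only 20 of 461 wild-type H3K36me2 islands had none while 1242 of 1559 Setd5+/- islands had none, and on the 16 other autosomes 2651 of 3643 wild-type islands (72.8%) had none. H3K4me3 was the other stable mark, with 2618 islands (11.5%) in wild type only and 3230 (13.9%) in Setd5+/- only. The corresponding counts were 5763 (30.9%) and 5001 (28.7%) for H3K27ac, 17586 (49.6%) and 6120 (25.2%) for H3K4me1, and 11302 (57.1%) and 8788 (46.8%) for H3K27me3. Of the wild-type H3K27me3 islands on chromosome X, 5897 of 8193 (72.0%) had no Setd5+/- island, and on autosomes only the order for this mark turned to 5400 and 7824. With both genotypes reduced to equal covered length, the order turned for H3K36me3 (1596 islands in wild type only and 1114 in Setd5+/- only), H3K4me3 (4165 and 1325), H3K4me1 (6840 and 10327) and H3K27me3 (4080 and 11014), and for H3K36me2 the counts were 3827 and 704.

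H3K36me3 over gene bodies was present in wild type only at Utp14a, needed for ribosomal RNA processing, at Cenpq of the centromere, at Cox18, which inserts a subunit of cytochrome oxidase, at Vps51 of the vesicle tether GARP, and at the splicing factor gene Syf2. Gpn3, Sphk2, Mydgf, Zfp689 and Pced1a followed the same pattern, each of the 10 covered over 100% of its span in wild type and 0% in Setd5+/- cells. They were the longest of 17 such genes. The reverse, from 0% to 100%, was seen at Cdca5, which encodes the cohesion factor sororin, at the lipid droplet gene Bscl2, at Amt of glycine cleavage, and at Wdr83 and Tmem230. It was also seen at Zfp992 on chromosome 4 and at Vxn, Actr1b, Chml and Rab29 on chromosome 1, and the 10 named were the longest of 12 such genes. Cdca5, from 6085097 on chromosome 19, lies near Vps51, which ends at 6077187 and went the other way. Among 16853 protein-coding genes of at least 5 kb, 5939 had H3K36me3 over at least 25% of the body in wild type and 6208 in Setd5+/- cells, 538 in wild type only and 807 in Setd5+/- only. Chromosome 1 supplied 135 of the 807 and 1 of the 538. Without chromosomes 1, 4, 15, X and Y the counts were 469 in wild type only and 522 in Setd5+/- only, and the mean covered percent was 26.7 and 25.9. At equal covered length the order turned, with 875 genes in wild type only and 593 in Setd5+/- only.

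H3K36me2 covered all of Cav2, a caveolin gene, all of the cilium gene Sntn, all of the placental prolactin genes Prl7b1 and Prl6a1 and all of Erv3 in wild type, and none of them in Setd5+/- cells. The dentin gene Dspp had 94.7% in wild type, Lrtm1 84.2%, Pdcl2 79.6% and Dhrs9 67.2%, each against 0%, and Glo1 of methylglyoxal detoxification had 100% against 36.1%. Of 59 genes that went from 0% to 100%, 48 lay on chromosome 1 and 6 on chromosome 4. The longest included the insulin receptor substrate gene Irs1, the cohesin protector gene Sgo2a, Mfsd6, Tmem182, Il1rl2, Ddx59 and Rgs13 on chromosome 1, and Tmeff1 and Stx17 near 48 Mb of chromosome 4. On the 16 other autosomes the 5 genes with this change, named after the values were seen, were Ogn, Omd, Tlr1, Prl8a8 and Actc1. Prl8a8 lies between Prl6a1 and Prl7b1 on chromosome 13, so genes of 1 region changed in opposite directions. H3K36me2 lay over at least 25% of 219 genes in wild type and 626 in Setd5+/- cells, of which 29 and 397 were on chromosome 1. Without chromosomes 1, 4, 15, X and Y the direction turned, with 174 genes in wild type and 88 in Setd5+/- cells.

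Hoxa2 and Hoxa3, regulators of hindbrain identity, carried H3K27ac at a gene end in Setd5+/- cells only, and Hoxa3 and Hoxa7 carried H3K4me3 in Setd5+/- cells only. The other genes with H3K4me3 at an end in Setd5+/- cells only and the longest coverage were Rag2, En1 on chromosome 1 and Tdrd7 on chromosome 4. H3K4me3 within 1 kb of an end in wild type only was longest at Cdkn1a, the cell cycle inhibitor gene, though Setd5+/- cells had an island of 473 reads inside the gene, beside one of 578 reads in wild type. It was next longest at Tafa1, followed by the adhesion gene Flrt2, the replication origin gene Orc4 and Cnih2. H3K27ac in wild type only was longest at the neural transcription factor genes Pou3f4 and Zic4, at the Notch ligand gene Dll1, and at H2-Ke6 and Tbc1d10a. Setd5+/- only H3K27ac also included Nnat, Gpr55 on chromosome 1 and Nfia on chromosome 4, and the Nfia difference turned to a decrease of 0.4 kb within 5 kb of its ends under a stricter island threshold. Among 21887 protein-coding genes, H3K4me3 lay within 1 kb of an end of 12973 genes in wild type and 12660 in Setd5+/- cells, 522 and 209 of them in that genotype only. H3K27ac marked 8156 and 7759 genes, 1349 and 952 in 1 genotype only, with 476 and 606 on chromosome 1. With an island required over the end base itself, the order for H3K27ac turned to 1183 and 1699 genes in 1 genotype only. H3K4me1 marked 7517 and 3687 genes, 4538 and 708 in 1 genotype only, which became 1915 and 1687 at equal covered length.

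H3K27me3 was present at the ends of Dlx1, a regulator of interneuron fate, Dbx1, a regulator of progenitor identity, Cdkn2a, which encodes the cell cycle inhibitors INK4A and ARF, and Cnpy1 and BC107364 in wild type only. They are the first by symbol of 24 genes in wild type only with the whole window of 10.0 kb covered. In Setd5+/- cells only it was longest at Colca2, Fam241a, Eml5, Dnm3 on chromosome 1 and Olfr270 on chromosome 4. It marked 1967 gene ends in wild type and 1567 in Setd5+/- cells, 824 and 424 in 1 genotype only. Chromosome X had 335 marked genes in wild type and 153 in Setd5+/- cells, and chromosome 1 had 118 and 185. On the 16 other autosomes 528 genes were marked in wild type only and 251 in Setd5+/- only. At equal covered length of the genotypes the order over all chromosomes turned, to 452 and 568 genes. Over gene bodies H3K27me3 marked 660 genes in wild type and 414 in Setd5+/- cells, of which 226 and 45 were on chromosome X.

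Of the Hox clusters, the Hoxa cluster differed between genotypes. H3K27me3 covered 99.4 kb of its 105.5 kb in wild type and 36.2 kb in Setd5+/- cells. H3K4me3 over the cluster covered 5.8 kb in wild type and 28.6 kb in Setd5+/- cells, and H3K27ac covered 2.2 and 30.0 kb. All 10 Hoxb, 9 Hoxc and 9 Hoxd genes kept H3K27me3 in both genotypes, and of these only Hoxc6 had H3K4me3 in Setd5+/- cells alone. The clusters were split after the values were seen.

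SETD5-V5 lay on genes with H3K36me3. Of its 6143 islands, 4925 (80.2%) overlapped a wild-type H3K36me3 island, 6.52 times the mean of 755 over 1000 shifts of the islands along their chromosomes, and 76.5% of its covered length lay inside H3K36me3. Overlap with H3K27ac was 751 islands, 1.12 times the shifted mean and at percentile 99.0. It was no longer set apart under the stricter threshold (percentile 95.8) or without chromosomes 1, 4, 15, X and Y (percentile 86.1). Overlap with H3K4me1 was 1186 islands, 1.00 times. Islands of SETD5-V5 overlapped H3K4me3 (595 islands, 0.641 times), H3K36me2 (128 islands, 0.383 times) and H3K27me3 (209 islands, 0.375 times) less often than all 1000 shifts. When 50% of a SETD5-V5 island had to be covered, only 10 islands met H3K4me3 and 12 met H3K27ac, and neither count was set apart from the shifts. Protein-coding genes held 83.1% of the SETD5-V5 covered length and 38.2% of the annotated chromosome span. A SETD5-V5 island lay within 1 kb of an end of 3602 genes, of which 3094 had H3K4me3, 2645 had H3K27ac and 106 had H3K27me3 in wild type. Over all 21887 protein-coding genes, 59.3% had H3K4me3, 37.3% had H3K27ac and 8.99% had H3K27me3 at an end. SETD5-V5 and the mark could lie at opposite ends of a gene, so these counts do not show that they overlap. The 10 islands with most reads held 8.82% of all SETD5-V5 island reads at a median of 141 reads per kb, against 17.7 over all islands. Of the 10, 7 lay within 1 kb of an end of a protein-coding gene. One covered Cwc22, another Sfi1 and another Speer4d and Speer4c. Those without a gene were the densest, at 1953, 4365 and 1435 reads per kb on chromosomes 9, 14 and 2. In at least 6 of the 12 histone mark lists, 5 of the 10 were also called. Whether these 10 islands mark SETD5 binding was not tested, and the series has no V5 library from untagged cells.

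**Figure D3:**
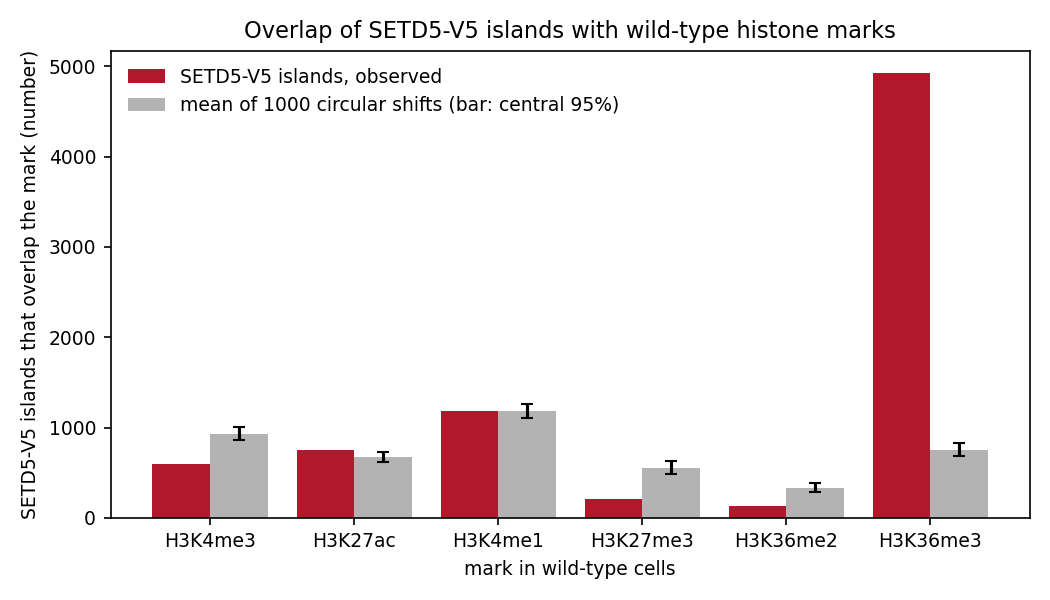
Number of SETD5-V5 islands that overlap each wild-type mark (bars) and the mean and central 95% of 1000 shifts. Overlap with H3K36me3 is 4925 islands against a shifted mean of 755.

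Genes with SETD5-V5 at an end had a smaller mean fall in H3K36me3 coverage than random lists matched on length and wild-type coverage. Those lists were drawn from all genes of a class, so they also held genes with SETD5-V5. Over 3379 such genes of at least 5 kb, the mean covered percent was 66.5 in wild type and 66.3 in Setd5+/- cells, a change of −0.20 against a central 95% of −5.18 to −4.21 for 10000 matched random lists. Coverage was lower in Setd5+/- cells at 1570 of these genes and higher at 1194. Without chromosomes 1, 4, 15, X and Y the change was −2.97, still above the −7.16 to −6.11 of matched lists. The call turned when genes were matched on length alone, where the same change lay at percentile 0.47 of the random lists. Most SETD5-V5 islands overlapped wild-type H3K36me3, so a second list from wild-type cells picked these genes. Matching used 5 classes of coverage and not island strength, and wild-type H3K36me3 islands without a partner had fewer reads. A smaller fall from stronger wild-type islands was therefore not told apart from a trait of the genes with SETD5-V5. For H3K36me2 the change at these genes was 2.82 percentage points, above the range of 1.19 to 1.95 for matched lists. On the same reduced set of chromosomes that change was −0.80 and lay inside the range of the random lists.

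Gene lists were chosen before the data were examined. None of the 15 lists had a mean change in H3K36me3 or H3K36me2 outside the central 95% of random lists of matched length, where chance gives 0.75. Both marks were averaged over list members of at least 5 kb only. These were 10 of 34 ribosomal protein genes, 15 of 39 Hox genes, 16 of 25 neural stem cell and radial glia genes and 19 of 26 neuronal differentiation genes. RNA polymerase II and splicing genes went from 82.9% to 77.1% covered by H3K36me3 (percentile 3.60), ribosomal protein genes from 89.0% to 76.0% (percentile 5.10) and cell cycle genes from 65.4% to 58.6% (percentile 5.32). Neural stem cell and radial glia genes had 51.0% and 52.5%, H3K36 methylation enzymes and readers 59.8% and 61.1%, HDAC3-NCoR and PAF1 complex genes 71.9% and 76.0%, and Polycomb and Trithorax genes 53.1% and 52.5%. Astrocyte and oligodendrocyte genes had 15.5% and 8.47%, axon guidance and adhesion genes 7.06% and 11.4%, neuronal differentiation genes 7.26% and 4.87%, synapse genes 5.85% and 5.71% and endothelium and mesenchyme genes 4.91% and 5.36%. Microglia and blood genes, Hox genes and non-neural lineage regulators had under 1% in both genotypes. Under a stricter island threshold cell cycle genes were set apart, with H3K36me3 coverage that fell by 13.9 percentage points (percentile 0.23). With no matching on length, cell cycle and ribosomal protein genes were set apart. The random lists were not matched on wild-type H3K36me3 coverage, which averaged 26.0% over all genes of at least 5 kb. Lists with high coverage had more to lose, so whether they fell more than genes of like coverage was not tested. Without chromosomes 1, 4, 15, X and Y, H3K36me2 of axon guidance and adhesion genes was set apart, and its change turned from 2.35 to −4.32 percentage points.

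H3K27me3 lay at 17 of 26 neuronal differentiation genes in wild type and 12 in Setd5+/- cells, with Rbfox3, Tbr1, Dlx1 and Dlx2 among the genes marked in wild type only. It lay at 39 and 32 of 39 Hox genes. Both net falls exceeded those of random lists, which start with few marked genes, but the share of marked genes in wild type only, 35.3% of the neuronal and 17.9% of the Hox genes, was below the 41.9% over all protein-coding genes. H3K4me3 was in Setd5+/- cells only at 5 of the 35 Hox genes without it in wild type (14.3%, against 2.34% over all such genes), and H3K27ac at 6 of 38 (15.8%, against 6.93%). Of these, 4 of the 5 and all 6 are neighbours in the Hoxa cluster, so the list result is that of 1 locus and random lists of separate genes are no measure for it. H3K4me1 lay at 29 of 34 ribosomal protein genes in wild type and 15 in Setd5+/- cells, and at 20 and 8 of 28 cell cycle genes, where 55.2% and 65.0% of the marked genes were in wild type only, close to the 60.4% over all genes. It lay at 7 and 1 of 12 HDAC3-NCoR and PAF1 genes, with 85.7% of the marked genes in wild type only, a fall no longer set apart under a stricter threshold. It lay at 4 and 5 Hox genes, with 50.0% of the marked genes in wild type only, and at 1 and 3 endothelium and mesenchyme genes, with none.

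SETD5-V5 was found at 21 of 32 RNA polymerase II and splicing genes, 12 of 34 ribosomal protein genes, 12 of 25 H3K36 methylation enzymes and readers, 10 of 25 neural stem cell and radial glia genes, 6 of 12 HDAC3-NCoR and PAF1 genes, 11 of 28 Polycomb and Trithorax genes and 9 of 28 cell cycle genes, each above the central 95% of random lists. It was found at none of the 39 Hox genes (percentile 0.675), where random lists of separate genes had 1 to 8 although Hox genes are neighbours in 4 clusters, and at none of the 20 non-neural lineage regulators (percentile 1.58), where they had 0 to 6, so the latter rests on ties at 0. It was found at 2 of 32 synapse genes, 2 of 36 axon guidance and adhesion genes, 1 of 26 neuronal differentiation genes, 1 of 20 astrocyte and oligodendrocyte genes, 1 of 18 endothelium and mesenchyme genes and none of 16 microglia and blood genes (percentile 2.995), inside the central 95% by percentile. The call ended under the stricter threshold for ribosomal protein genes (3 genes), cell cycle genes (7 genes) and non-neural lineage regulators (percentile 3.20). It ended without chromosomes 1, 4, 15, X and Y for cell cycle and Hox genes. The random lists were matched on gene length and not on H3K36me3, which most SETD5-V5 islands overlapped. Mean wild-type H3K36me3 coverage of the 7 lists above the central 95%, over their members of at least 5 kb only, ran from 51.0% to 89.0%. It was 26.0% over all genes of at least 5 kb, and 0.0% for Hox genes and non-neural lineage regulators of that length. Placement on particular gene classes was therefore not separated from placement on genes with H3K36me3.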

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

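The setting without chromosomes 1, 4, 15, X and Y was chosen after the data were seen. Leaving out libraries was not possible and no paired analysis was possible, because each group has 1 library. Of 253 comparisons with alternatives, 182 stayed within the limits used (a count within 1.5 times, a percentile on the same side of the central 95%), 65 moved, 2 lost their call and 4 reversed. Each count was judged singly by size, so a turn in the order of wild type only and Setd5+/- only is not among the 4. At equal covered length the order turned for H3K4me3, H3K4me1, H3K27me3 and H3K36me3 islands, for H3K27me3 at gene ends (568 in Setd5+/- only) and for H3K36me3 over bodies (593 in Setd5+/- only). It also turned for H3K27ac with an island over the end base, for H3K27me3 islands on autosomes only (7824 gained), and for H3K36me2 over bodies without chromosomes 1, 4, 15, X and Y (144 in wild type only). Where no reason is given, the cause was not tested. Depth outside the islands is unknown, so an island missing from a list is not shown to lack the mark. Of 639 values of single lists and genes, 594 stayed the same, 18 moved, 14 lost a call, 11 gained one and 2 reversed. The overlap of SETD5-V5 with H3K36me3 lay between 6.52 and 10.5 times the shifted mean in all settings run.

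Under the stricter threshold, H3K4me3 islands lost and gained were 1379 and 1807, since the weakest islands were dropped from each list. SETD5-V5 overlap with H3K27ac was 1.09 times the shifted mean and no longer set apart. H3K36me3 changes set 1 gene list apart (cell cycle) and H3K4me3 changes 2. Nfia changed direction for H3K27ac under this setting and under equal covered length, at −0.4 kb in both.

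With 50% reciprocal overlap, more islands lacked a partner by construction: 9241 lost and 8033 gained for H3K27ac, 10630 gained for H3K4me1, 14306 gained for H3K27me3, and 2930 lost and 3993 gained for H3K36me3. With islands within 3 kb merged first, 6884 H3K27me3 islands were lost and 5553 gained, since fewer islands were counted.

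On autosomes only, wild-type H3K27me3 had 11593 islands, of which 5400 were lost, and 179 genes had it over the body in wild type only, because the X islands were left out.

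At equal covered length, H3K4me3 islands lost and gained were 4165 and 1325, H3K4me1 islands 6840 and 10327, and H3K36me3 islands 1596 and 1114. H3K27me3 had 4080 lost and 11014 gained, and H3K36me2 3827 lost and 704 gained. At gene ends, 134 genes had H3K4me3 in Setd5+/- only, 2071 had H3K27ac in wild type only, 452 had H3K27me3 in wild type only, and 1915 and 1687 had H3K4me1 in wild type only and Setd5+/- only. Over bodies, 875 genes had H3K36me3 in wild type only, 329 had H3K36me2 in Setd5+/- only and 228 had H3K27me3 in wild type only.

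With an island over the end base itself, Setd5+/- only genes were 434 for H3K4me3, 1699 for H3K27ac (against 1183 in wild type only), 269 for H3K27me3 and 422 for H3K4me1, and wild type only genes were 1324 for H3K4me1.

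At a body share of 10%, wild type only genes were 402 for H3K36me2 and 582 for H3K27me3, and Setd5+/- only genes were 244 for H3K27me3. At 50% these counts were 34, 137 and 54. Among genes overlapping no other gene, wild type only and Setd5+/- only counts were 267 and 390 for H3K36me3, 71 and 253 for H3K36me2, and 223 and 73 for H3K27me3, since fewer genes were tested.

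When 50% of a SETD5-V5 island had to be covered, overlap with H3K4me3 was 1.04 times and with H3K27ac 0.833 times the shifted mean, because few narrow islands cover a broad one. Matched on length alone, the H3K36me3 change at genes with SETD5-V5 was −0.20 as before, but at percentile 0.47. Mean wild-type coverage was 66.5% at genes with SETD5-V5 and 26.0% over all genes of at least 5 kb. Whether this gave the turn was not tested. With no matching on gene length, H3K36me3 changes set 2 lists apart and H3K4me3 changes 2.

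Without chromosomes 1, 4, 15, X and Y, gained islands were 2737 for H3K27ac, 3275 for H3K4me1, 4455 for H3K27me3, 833 for H3K36me2 and 1166 for H3K36me3, and 4794 H3K27me3 islands were lost. At gene ends, H3K27me3 marked 528 genes in wild type only and 251 in Setd5+/- only, and H3K4me1 marked 409 in Setd5+/- only. Over bodies, Setd5+/- only genes were 522 for H3K36me3, 58 for H3K36me2 and 75 for H3K27me3, and wild type only genes were 159 for H3K27me3. SETD5-V5 overlap with H3K27ac was 1.05 times the shifted mean and no longer set apart, and the H3K36me2 change at SETD5-V5 genes was −0.80. H3K36me2 changes set 1 list apart (axon guidance and adhesion, −4.32 percentage points) and H3K4me3 changes 2.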

Other observations

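The tests of extra chromosome copies and of library depth on the chromosome pattern, and the look at the Cdkn2a, Cdkn1a, Xist and Y-linked loci, and at SETD5-V5 density by chromosome, were chosen after the result was seen.

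Over Cdkn2a on chromosome 4 (89274473 to 89294619), outside the 30 to 80 Mb part, H3K27me3 covered 19.1 kb of the 20.1 kb in wild type and none in Setd5+/- cells. Inside the gene H3K4me3 covered 4.02 kb in wild type and 8.42 kb in Setd5+/- cells, and H3K27ac covered 0.0 and 7.82 kb. Cdkn1a on chromosome 17, 9.74 kb long, had 5.42 and 3.40 kb of H3K4me3, and 4.72 kb of H3K36me3 in wild type against none in Setd5+/- cells, while H3K27ac covered 3.22 and 3.02 kb. Genes with both H3K4me3 and H3K27me3 at an end numbered 1075 in wild type and 695 in Setd5+/- cells, and of the 578 with both in wild type only, 428 kept H3K4me3 and 91 kept H3K27me3. Chromosome X supplied 121 of the 578, with 165 such genes in wild type and 60 in Setd5+/- cells, chromosome 1 had 64 and 78, and counts at equal covered length were not computed for this pair of marks. Over all protein-coding genes, 12451 of 12973 kept H3K4me3 and 1143 of 1967 kept H3K27me3. The pair was thus more often lost through H3K27me3, as that mark was lost more often over all genes. Both marks need not lie at the same end of a gene.

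Islands on chromosomes 1 and 15 and on part of 4 covered more in Setd5+/- cells, relative to other autosomes, in every mark. A difference in depth or enrichment between the libraries would act alike on islands of like strength, whereas among shared islands matched on wild-type read density the log2 density ratio of chromosome 1, from 0.15 for H3K27me3 to 0.34 for H3K36me3, had a 95% interval above all 16 other autosomes in 6 of 6 marks. A change at the genes that carry SETD5-V5 is argued against by chromosome 1 H3K4me3 islands with no SETD5-V5 island within 50 kb, whose median log2 density ratio was 0.30 (95% bootstrap interval 0.27 to 0.34, n = 629), beside 0.29 for the other 615. A candidate explanation is extra copies of these chromosomes in the Setd5+/- culture. The log2 density ratio on chromosome 1 was above 0.1 in 6 of 6 marks. That bound was set after the values were seen, so it restates the pattern and is no test of extra copies. Whether copy number departs from the usual at all, in which culture, and whether the genotype plays a part, stays open. Copy number was not measured, and SETD5-V5 in wild-type cells also had raised log2 density ratios against wild-type H3K36me3, a comparison across antibodies. They were 0.14 on chromosome 1, 0.11 on chromosome 15 and 0.14 on 30 to 80 Mb of 4. The ratio was 0.09 on X, which is not raised for H3K36me3 in Setd5+/- cells (−0.01), and −0.04 to 0.03 on the 16 other autosomes.

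H3K27me3 on chromosome X covered less in Setd5+/- cells, while Xist had H3K4me3 islands of 915 reads in wild type and 910 in Setd5+/- cells, and no island of any mark lay over Kdm5d, Eif2s3y, Uty or Ddx3y in either genotype. Lower depth or enrichment of the Setd5+/- H3K27me3 library is argued against as the whole reason, since after the wild-type list was trimmed to equal autosomal coverage the log2 ratio of X was −0.78, below the −0.25 to 0.48 of the other autosomes. H3K27me3 islands of X shared by both genotypes showed no fall in density. Their median log2 density ratio, relative to the other autosomes, was −0.008 (bootstrap interval −0.027 to 0.013, n = 1607). Islands without a Setd5+/- partner have no such ratio, so these values do not cover the islands that were lost. Loss of the inactive X in part of the Setd5+/- cells may still contribute. It cannot be told apart from a change of the mark itself here. The log2 density ratio of islands over Xist had a median of 0.076, which met the bound set against such a loss and not the bound set for it. The ratio ran from −0.30 to 0.71 over 4 marks, so its median does not decide the question.

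Together, autosomes other than 1, 4 and 15 had less H3K36me2 coverage in Setd5+/- cells, but chromosome 13 had more (5.99 against 5.63 Mb). Less coverage is the direction that lower methylation would give. A higher read threshold of the Setd5+/- H3K36me2 list could also give it. The lowest values of that list were higher, at 75 reads per island and 14.1 reads per kb, against 38 and 11.9 in wild type. Total reads are unknown, so whether the threshold was also higher relative to depth is not known. Of the wild-type islands with most reads, 57.1% (n = 917) had no Setd5+/- island, against 79.4% of those with fewest (n = 912), a value between the bounds set for and against a threshold. The loss was therefore neither limited to weak islands nor independent of their strength, and methylation cannot be told apart from the threshold with these lists.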
